A study of Mus musculus with 12 samples.

How the data were processed

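The data were 12 RNA-seq libraries of B cells from the jejunum of 6 C57BL/6J mice (8 to 12 weeks old) with experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis in which immunization against a myelin protein starts an autoimmune attack on the central nervous system. Per the labels' protocols, mice were immunized with residues 35 to 55 of myelin oligodendrocyte glycoprotein in complete Freund's adjuvant, received pertussis toxin on days 0 and 2, and were sampled 7 days after immunization. Viable CD45+ cells without CD11b, F4/80 and CD11c and with B220 were sorted by flow cytometry into LYVE-1+ and LYVE-1- fractions, which gave 6 libraries of each. LYVE-1 is a hyaluronan receptor best known from lymphatic endothelium. Per the labels, libraries were made with a SMART-seq kit, which amplifies cDNA before sequencing, from 10 ng of RNA, except in mouse 2, where the LYVE-1- library had 4.02 ng and the LYVE-1+ library 6.9 ng.

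The authors deposited whole-number read counts per gene for each library. Per the submitters' processing notes, the tools named were cutadapt 1.8, STAR 2.5.3a and HTSeq 0.9.1 and the genome build was GRCm38. The annotation release and the strand setting of the counting were not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. Reads that align to several places were held in a row of their own in the deposited counts, so genes with near-identical copies can be undercounted. The 5 rows that name no gene held 36.9% to 39.9% of all reads per library, most of them aligned to several places, and were left out of library sizes and tests. Counts in genes ranged from 21772937 to 30058942 per library. Replicate libraries of one group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of at least 9.98. Reads carried no molecular identifiers that the sources mention, so counting intervals cover counting error only.

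Gene symbols, coordinates and biotypes came from GENCODE M21 on GRCm38, which matched 55141 of the 55401 gene identifiers in the files. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 14493, and scaled by the trimmed mean of M-values. Differences between LYVE-1+ and LYVE-1- libraries were tested with edgeR 4.0.16 (robust quasi-likelihood F test) in R 4.3.3, with group as the one term and Benjamini-Hochberg adjustment. A gene with an adjusted p under 0.05 was called. Log2 fold changes are LYVE-1+ over LYVE-1-, with standard errors taken from the F statistic. CPM values were computed on the scaled library sizes.

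The 2 fractions shared mouse numbers. The design text states that both were sorted from the same 6 mice, and the numbers were therefore taken as pairs. Deviations from the group means correlated between libraries of the same mouse with r from 0.155 to 0.417, against -0.38 to 0.187 for different mice, and 11 of 12 libraries correlated best with their own number. The fit with mouse as a block was the alternative, and it called 6399 genes.

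For 43 gene lists fixed before the data were examined, measured members were counted as called higher, called lower or not called, over all genes tested and adjusted over the list alone. The 41 lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, two-sided) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, a rotation test of whether the members move on balance one way. List medians are medians of the difference in mean log2 CPM on this scale, which draws low genes toward 0. Shares of counts and of reads, and genes detected after thinning each library to 21772937 counts, were compared with two-sided exact permutation tests over all 924 assignments, for which the smallest possible p is 0.00216. These tests formed a family of 16, with Benjamini-Hochberg adjusted values beside the raw p. Mouse pairs were tested by exact sign-flip permutation over 64 patterns, for which the smallest possible p is 0.03125. The adjusted values belong to the unpaired tests, and the paired p values were not adjusted over the 16. The unpaired assignments do not keep mouse pairs together, and no paired p was shown to pass the threshold after adjustment.

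The rule for named genes was fixed before the data were examined. It took the transcripts of the sort markers and, among called genes with a mean log2 CPM of at least 1 and one direction in at least 5 of 6 mice, the 10 largest rises and 10 largest falls. Variable, diversity and joining segments of antigen receptors, pseudogenes and predicted gene models were left out. It also took the 5 genes with the smallest p in each direction and 2 to 4 members with the smallest p from each list described. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

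On simulated counts for the comparison of the 2 fractions, with 14493 genes of which 50 were changed at each size, edgeR recovered 32 genes at a fold of 1.5, 37 at 2, 49 at 4 and 49 at 16, with 13 false calls. On simulated data camera called the planted list and 0 of 40 lists without a change. Changed genes were drawn only from those with a mean log2 CPM above 0, so recovery of lower genes was not measured. Far fewer genes were changed than were called in the data. Simulated genes were drawn independently of each other and without mouse effects. Such data cannot show how often camera calls lists whose genes vary together. Alternatives changed the tool (DESeq2 1.42.0, limma-voom), the scaling, the filter, the depth, the genes entered, the libraries entered and the covariates, including a surrogate variable from sva 3.50.0. Some alternatives were chosen after seeing the data, namely the block together with a correction for GC content and transcript length, leaving out mouse 6, and the share of reads in no annotated gene as a covariate. GC content and length were known for 14478 of the 14493 tested genes.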

Results

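Gene expression was measured by RNA-seq in B220+ cells sorted from the jejunum of 6 mice, 7 days after immunization for experimental autoimmune encephalomyelitis. Each mouse gave a LYVE-1+ and a LYVE-1- library, so that 6 libraries stood in each group. Counts in genes ranged from 21772937 to 30058942 per library (median 27192201). They were lower in the LYVE-1+ library of 4 of 6 mice, and the difference between the groups did not pass the threshold in an exact permutation test (p = 0.606, adjusted p = 0.646). Libraries of mouse 2 were made from less RNA than the others.

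The comparison asked how intestinal B cells that carry LYVE-1 on their surface differ in their transcripts from those that do not. The series title places these cells in the context of intestinal angiogenesis and the gut-brain axis. Cell cycle, germinal centre, IgA and lymphatic endothelial transcripts were higher in the LYVE-1+ libraries. Transcripts of T cells, NK cells, plasmacytoid dendritic cells and fibroblasts were lower. With edgeR, 4734 of 14493 genes were called at an adjusted p under 0.05, of which 2546 were higher and 2188 lower in LYVE-1+ libraries. Changes of over 2-fold were found for 526 of the higher and 546 of the lower genes. With upper-quartile scaling the share of higher genes among the calls was 41.1%, against 53.8% with the scaling used here. Counts were 7230 with limma-voom and mouse as a block, 713 for changes tested against a fold of 1.5, and 348 with the share of reads in no annotated gene as a covariate, an alternative chosen after seeing the data, under which Lyve1 kept its call (adjusted p = 0.0385), and of 127 other called genes followed through the alternatives 45 kept their call and 127 their direction. The first principal component held 52.8% of the variance and separated the groups.

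**Figure D1:**
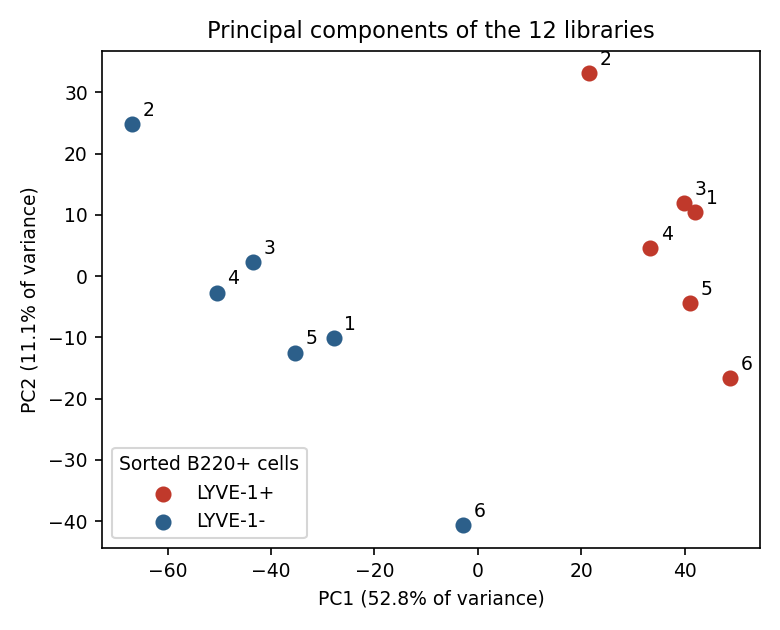
Scores of the 12 libraries on the first (horizontal, 52.8% of variance) and second (vertical, 11.1%) principal components of log2 CPM, with one point per library, coloured by sorted fraction and numbered by mouse. The LYVE-1+ libraries lie at 21.5 to 48.8 on the first component and the LYVE-1- libraries at -66.8 to -2.8, with that of mouse 6 nearest to the LYVE-1+ libraries.

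The Lyve1 transcript followed the sort. Lyve1 (ENSMUSG00000030787; GRCm38 chromosome 7, 110850607 to 110863239, minus strand) stood at 11.03 ± 5.70 CPM (SD, n = 6) in LYVE-1+ and 0.378 ± 0.49 CPM (SD, n = 6) in LYVE-1- libraries, with a log2 fold change of 4.95 ± 0.69 (SE; edgeR adjusted p = 0.000246) and higher values in LYVE-1+ cells of 6 of 6 mice. Raw counts ranged from 0 to 511. Among the other sort markers, Ptprc, which encodes CD45 and its B220 isoform, had a log2 fold change of -0.14, Itgam (CD11b) -0.01, Adgre1 (F4/80) 0.01 and Itgax (CD11c) -0.70, and these 4 were not called. With mouse as a block Ptprc was called (log2 fold change -0.13, adjusted p = 0.0261). The values of Itgam and Adgre1 changed sign when single libraries were left out, and that of Adgre1 also under upper-quartile scaling and under library totals alone.

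Genes of lymphatic endothelium rose with Lyve1. Of 13 measured members of the lymphatic endothelial list 9 were higher and 1 lower, over all genes and adjusted over the list alone, with a median difference of 1.53 in log2 CPM (camera adjusted p = 6.43e-05). The adjusted p was 0.222 with an estimated correlation. Ccl21a, a chemokine that guides CCR7-bearing cells, rose by a log2 fold change of 4.43 ± 0.37 and Mmrn1, a multimerin of endothelium and platelets, by 4.58 ± 0.62 (SE). Reln (1.53) and Ackr2 (1.57), an atypical chemokine receptor, rose less. Prox1, the transcription factor that specifies lymphatic endothelium, rose by 1.68, and Thy1 was the member that fell (-2.08). Both were chosen after their values were seen. Ccl21a has near-identical copies in the mouse genome, so its counts are uncertain. Flt4, the VEGF-C receptor, rose by 3.49 ± 0.67, and the other members of the 10 largest rises included Cyp4b1 (3.51), the water channel Aqp1 (3.17), the caveolar gene Cavin2 (2.77), the cation channel Trpm5 (2.25) and the natriuretic peptide receptor Npr2 (2.20). These genes were low in absolute terms: Mmrn1 reached 30.9 ± 20.6 CPM and Ccl21a 10.7 ± 4.06 CPM (SD, n = 6) in LYVE-1+ libraries. The blood endothelial list went both ways, with 6 of 18 members higher and 4 lower over all genes, and 7 and 4 adjusted over the list alone. Emcn rose by 2.33 and Pecam1, which B cells also express, fell by 0.29 on the log2 scale. That list was not called (camera adjusted p = 0.953), and its median was below 0 while its mean was above 0.

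**Figure D2:**
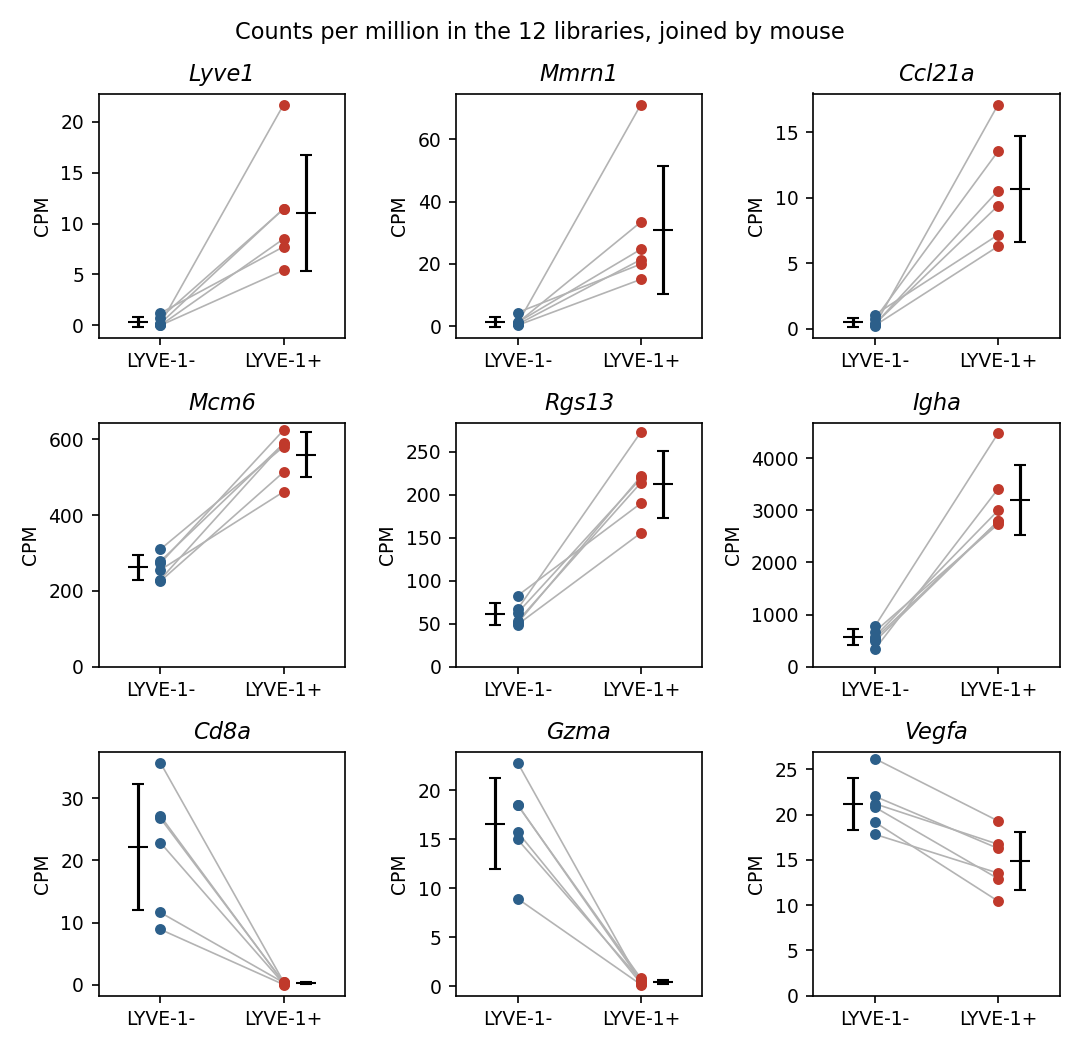
CPM of 9 genes in LYVE-1- and LYVE-1+ libraries, with one point per library, grey lines joining the libraries of one mouse, and black bars giving the mean and SD of 6 libraries. Lyve1, Mmrn1, Ccl21a, Mcm6, Rgs13 and Igha are higher and Cd8a, Gzma and Vegfa lower in the LYVE-1+ library of each of the 6 mice.

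Cell cycle genes rose almost throughout. Of 36 measured members 35 were higher and 0 lower, over all genes and adjusted over the list alone, with a median difference of 1.49 in log2 CPM (camera adjusted p = 1.9e-23; adjusted p = 0.222 with an estimated correlation). The replication helicase genes Mcm6 (log2 fold change 1.10 ± 0.09, SE), Mcm3 (1.03 ± 0.09) and Mcm7 (1.08 ± 0.10) had the smallest p in the list. Mcm6 stood at 560 ± 60.3 CPM in LYVE-1+ and 262 ± 31.8 CPM in LYVE-1- libraries (SD, n = 6). The proliferation marker Mki67, chosen after its value was seen, rose by 1.59. Dtl, which acts in replication licensing, rose by 1.21 and was among the 5 rises with the smallest p, with Krt222 (1.02), Ehf (1.82) and the adenosine deaminase gene Ada (1.44).

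Germinal centre genes rose with the cell cycle. Germinal centres are the sites where B cells divide and mutate their antigen receptors. Of 15 measured members 13 were higher and 1 lower, over all genes and adjusted over the list alone, with a median difference of 1.39 in log2 CPM (camera adjusted p = 1.71e-07; adjusted p = 0.296 with an estimated correlation). Rgs13, a regulator of G-protein signalling, rose from 60.7 ± 12.8 to 212 ± 38.8 CPM (SD, n = 6), a log2 fold change of 1.804 ± 0.15 (SE). Fas rose by 1.23 ± 0.15 and Mef2b by 1.41 ± 0.17 (SE). S1pr2, which confines B cells to the follicle, rose by 1.49 and Cd83 fell by 0.19 on the log2 scale. Both were chosen after their values were seen. The adjusted p of Cd83 was between 0.0501 and 0.0647 without the LYVE-1- library of mouse 3, 4 or 6 or the LYVE-1+ library of mouse 1, 3 or 5. The share of reads in no annotated gene may reflect unspliced RNA or RNA quality but measures neither directly. This share moved with the groups, at 8.79% ± 0.87 in LYVE-1+ and 11.1% ± 0.79 in LYVE-1- libraries (SD, n = 6; exact permutation p = 0.00216, adjusted p = 0.00693). Tested by mouse pairs this share stood at the smallest possible p (exact sign-flip p = 0.03125, unadjusted). Markers of T and NK cells, a further difference between the groups, were lower in the LYVE-1+ libraries.

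**Figure D3:**
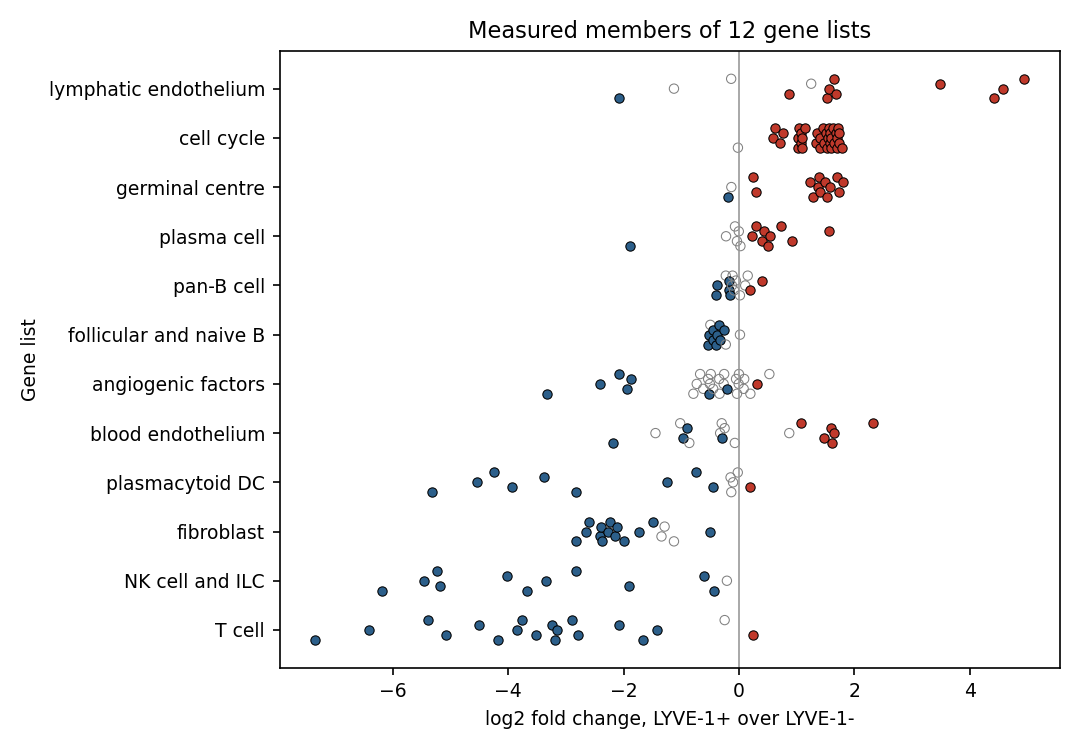
Fitted log2 fold change (horizontal, LYVE-1+ over LYVE-1-) of each measured member of 12 gene lists (vertical), with one point per gene. Filled red points are called higher, filled blue points called lower and open points not called at an adjusted p under 0.05. 35 of 36 cell cycle genes are called higher and 17 of 19 T cell genes are called lower. The vertical offset within a list only separates points.

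Isotype use differed. IgA took 29.7% ± 5.31 of heavy-chain constant counts in LYVE-1+ and 6.89% ± 2.21 in LYVE-1- libraries (SD, n = 6; exact permutation p = 0.00216, adjusted p = 0.00693), and it was higher in LYVE-1+ cells of 6 of 6 mice. The share of IgM was lower, at 48.5% ± 4.41 against 62.1% ± 3.02, as was that of IgD, at 11.9% ± 1.24 against 21.3% ± 1.18 (SD, n = 6; exact permutation p = 0.00216 and adjusted p = 0.00693 for each). Shares of one total are tied, so the rise of IgA by itself lowers the others. In the immunoglobulin constant list the 2 genes called lower were Ighd and Ighg1, and Ighm was not called lower. IgG1 fell from 4.40% ± 2.24 to 1.15% ± 0.61 (exact permutation p = 0.00649, adjusted p = 0.013), while IgG2b rose from 4.66% ± 1.20 to 7.44% ± 2.13 (SD, n = 6; exact permutation p = 0.0216, adjusted p = 0.0346) and IgG3 from 0.383% ± 0.15 to 0.933% ± 0.22 (SD, n = 6; exact permutation p = 0.00433, adjusted p = 0.00989). IgG3 was higher in 5 of 6 mice and missed the threshold when tested by mouse pairs (exact sign-flip p = 0.0625). By mouse pairs IgA, IgM, IgD, IgG1, IgG2b and all immunoglobulin genes together each stood at the smallest possible p (exact sign-flip p = 0.03125, unadjusted). IgG2c was at 0.375% and 0.273% (exact permutation p = 0.37, adjusted p = 0.46). Reads of Ighg2b and Ighg2c overlap in sequence and their split is uncertain. All immunoglobulin genes together took 2.15% ± 0.14 of counts in LYVE-1+ and 1.58% ± 0.11 in LYVE-1- libraries (SD, n = 6; exact permutation p = 0.00216, adjusted p = 0.00693).

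**Figure D4:**
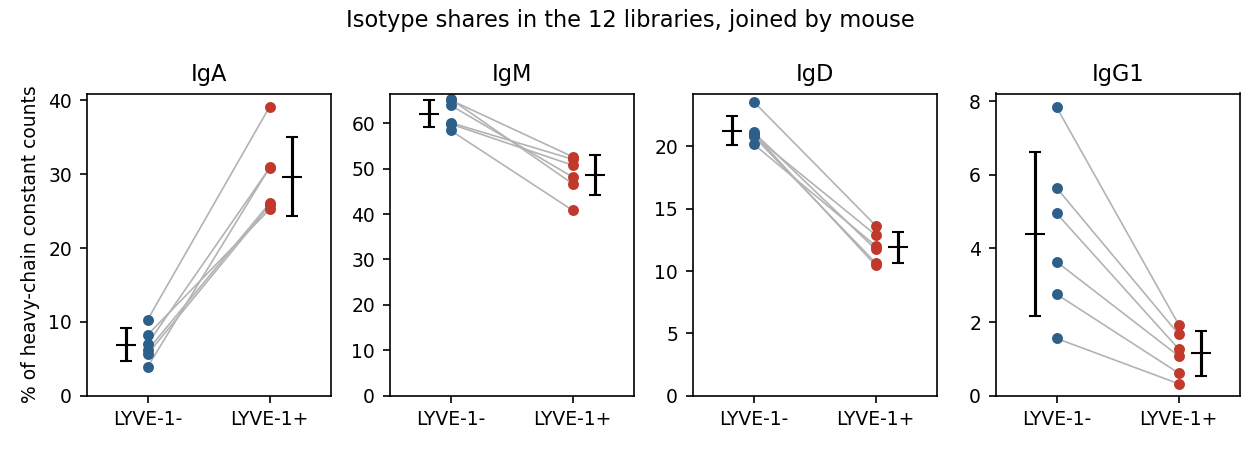
Shares of IgA, IgM, IgD and IgG1 in heavy-chain constant counts (vertical, percent) in LYVE-1- and LYVE-1+ libraries, with one point per library, grey lines joining the libraries of one mouse, and black bars giving the mean and SD of 6 libraries. The IgA share lies between 25.3% and 39.2% in LYVE-1+ and between 3.92% and 10.3% in LYVE-1- libraries.

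Among single genes of this group, Igha rose by a log2 fold change of 2.51 ± 0.19 (SE; edgeR adjusted p = 6.2e-06), to 3200 ± 674 CPM from 562 ± 152 CPM (SD, n = 6). Jchain, which joins IgA and IgM monomers, rose by 1.57 ± 0.14 and the light-chain gene Iglc1 by 1.00 ± 0.14, while Ighd fell by 0.46 on the log2 scale. Ighg2b (1.05) and Ighg3 (1.66) rose and Ighg1 fell (-1.57). These 3 were chosen after their values were seen. The call of Ighg1 was lost without the LYVE-1+ library of mouse 1 (adjusted p = 0.0531) and without the LYVE-1- library of mouse 3 (0.0546) or mouse 6 (0.0551), and also without a filter (0.0604) or without mouse 2 (0.0560). Of 13 measured members of the immunoglobulin constant list 6 were higher and 2 lower, over all genes and adjusted over the list alone (median difference 0.52 in log2 CPM, camera adjusted p = 0.0119; adjusted p = 0.222 with an estimated correlation). The plasma cell list, which shares Jchain with it, had 9 of 15 members higher and 1 lower, Ly6c2 (-1.89), by both adjustments (median difference 0.30, camera adjusted p = 0.00889; adjusted p = 0.222 with an estimated correlation). Slamf7 rose by 0.54 and Derl3, of the endoplasmic reticulum, by 0.74. The number of genes detected at equal depth was lower in LYVE-1+ libraries, at 20836 ± 108 against 21344 ± 262 (SD, n = 6; exact permutation p = 0.00433, adjusted p = 0.00989). Tested by mouse pairs this number stood at the smallest possible p (exact sign-flip p = 0.03125, unadjusted).

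Genes of follicular and naive B cells fell by small amounts. Of 12 measured members 9 were lower and 0 higher over all genes, and 11 were lower adjusted over the list alone (median difference -0.40 in log2 CPM, camera adjusted p = 1.31e-05; adjusted p = 0.222 with an estimated correlation). Zfp318, which allows IgD to be made, fell by 0.53 on the log2 scale and Il4ra by 0.44. The pan-B cell list held 2 rises and 5 falls among 15 members over all genes, and 2 and 6 adjusted over the list alone, with a median difference of -0.11, and was not called (camera adjusted p = 0.306). Ms4a1 (CD20) rose by 0.19 and the coactivator gene Pou2af1 by 0.41, and Fcer2a (CD23) fell by 0.40 and Bank1 by 0.37 on the log2 scale. In the memory and atypical B cell list 4 of 12 members were higher and 7 lower by both adjustments (camera adjusted p = 0.695), with Nt5e (CD73) up by 1.02 and Zbtb32 by 1.40. In the marginal zone and B1 list 3 of 16 were higher and 5 lower by both adjustments (camera adjusted p = 0.503), with Cd5 down (-1.42) and Fcrl5 up (0.51). Cd5 is also a member of the T cell list, most of whose genes fell. In the regulatory B cell list 5 of 16 were higher and 8 lower by both adjustments (camera adjusted p = 0.306), with falls of Gzmb (-4.03) and Tigit (-3.34), which T and NK cells also express. Il10, chosen after its value was seen, rose by 1.64 ± 0.29 (SE) at a mean of 3.57 CPM in LYVE-1+ libraries.

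T cell and NK cell transcripts were the largest falls. Of 19 measured T cell genes 17 were lower and 1 higher, by both adjustments, with a median difference of -3.14 in log2 CPM (camera adjusted p = 1.1e-14; adjusted p = 0.222 with an estimated correlation). Of 12 measured NK cell and innate lymphoid genes 11 were lower and 0 higher, by both adjustments, with a median of -3.10 (camera adjusted p = 3.1e-09; adjusted p = 0.222 with an estimated correlation). The cytotoxic granule gene Gzma fell from 16.6 ± 4.64 to 0.448 ± 0.24 CPM (SD, n = 6; log2 fold change -5.18 ± 0.30, SE; edgeR adjusted p = 1.2e-06) and Cd8a from 22.2 ± 10.2 to 0.253 ± 0.16 CPM (SD, n = 6; log2 fold change -6.42 ± 0.49, SE). Cd3d fell by 3.76, Trbc1 by 4.17, Lat by 1.66, Eomes by 5.46 and Nkg7 by 6.19 on the log2 scale. Lck, the member that was higher (0.25), was chosen after its value was seen and is also expressed in B cells. Its call was lost without the LYVE-1- library of mouse 1 or 5 or the LYVE-1+ library of mouse 1 or 3, with adjusted p from 0.0501 to 0.0643. The gamma-delta T cell receptor genes Trdc (-7.35), Tcrg-C1 (-6.86), Tcrg-C2 (-8.27) and Tcrg-C4 (-6.95) were among the 10 largest falls, with Ikzf2 (-6.59), Cd7 (-6.43) and Kit (-6.08). Klra7 was first among them, with 1467 counts over the LYVE-1- libraries and 3 over the LYVE-1+ libraries, a ratio of 472 with an exact 95% counting interval of 161 to 2293. All 3 counts came from mouse 5, the other 5 LYVE-1+ libraries had 0, and 757 of the 1467 came from the LYVE-1- library of mouse 2. The constant genes of the gamma chain and the Klra genes are families of similar sequence, so the values of their members are uncertain. Cst7 (-4.87) and the chemokine gene Ccl5 (-5.87) were among the 5 falls with the smallest p.

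Transcripts of plasmacytoid dendritic cells, fibroblasts, pericytes and erythroid cells were also lower. Of 14 measured plasmacytoid dendritic cell genes 9 were lower and 1, Tcf4, higher (0.19, chosen after its value was seen), by both adjustments (median difference -0.91, camera adjusted p = 0.000367; adjusted p = 0.296 with an estimated correlation). Smim5 fell by 3.39 and Cox6a2 by 3.94 on the log2 scale. Plasmacytoid dendritic cells carry B220. Of 17 fibroblast genes 14 were lower and 0 higher over all genes, and 15 lower adjusted over the list alone (median difference -2.10, camera adjusted p = 4.4e-05; adjusted p = 0.494 with an estimated correlation), with Col6a2 at -2.65 and Igfbp7 at -1.99. Extracellular matrix genes had 14 of 28 members lower and 0 higher over all genes, and 16 lower adjusted over the list alone (median difference -0.77, camera adjusted p = 0.00394; adjusted p = 0.590 with an estimated correlation), with Fbln5 at -1.89 and Mmp14 at -1.87. The mean log2 CPM of these genes was lower in LYVE-1+ cells of 5 of 6 mice. In mouse 6 it was higher, at 1.19 in LYVE-1+ against 1.04 in LYVE-1- cells. The list median was -1.22 without the LYVE-1- library of mouse 6. Its call was lost with the share of reads in no annotated gene as a covariate (adjusted p = 0.316), and fry did not call the list (adjusted p = 0.0658). Of 9 pericyte and smooth muscle genes 5 were lower by both adjustments (median difference -1.09, camera adjusted p = 0.0154; adjusted p = 0.494 with an estimated correlation), and this call was lost without the LYVE-1+ library of mouse 5 (adjusted p = 0.0518). The mean log2 CPM of the pericyte and smooth muscle genes was lower in LYVE-1+ cells of 5 of 6 mice. Pdgfrb stood at -1.48 and Rgs5 at -1.51. The call of Rgs5 was lost without the LYVE-1- library of mouse 3 or the LYVE-1+ library of mouse 1, 5 or 6, with adjusted p from 0.0517 to 0.0602, and without a filter (0.0538). Of 6 erythroid and platelet genes 5 were lower by both adjustments (median difference -1.10, camera adjusted p = 0.0136; adjusted p = 0.494 with an estimated correlation), among them the globin genes Hba-a2 (-1.38) and Hbb-bs (-1.21), whose paralogs share reads and whose values are therefore uncertain. The macrophage and monocyte list was not called (1 of 15 members higher and 2 lower by both adjustments, camera adjusted p = 0.859). Ccr2 fell by 2.94 and Ly6c2 by 1.89 on the log2 scale, and Stab1, also found in lymphatic endothelium and chosen after its value was seen, rose by 2.09. The conventional dendritic cell list was not called either (1 of 12 higher and 3 lower by both adjustments, camera adjusted p = 0.195), with Itgae (-4.18) and Cd209a (-3.36) lower and Flt3 higher (0.44, chosen after its value was seen). That list passed the threshold without the LYVE-1- library of mouse 6 or without the LYVE-1+ library of mouse 1, 2, 3, 4 or 6, with adjusted p from 0.0179 to 0.0394.

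Angiogenic factor genes, which bear on the subject named in the series title, were lower on balance, although most members were not called. Of 28 measured members 7 were lower, 1 higher and 20 not called, by both adjustments, with a median difference of -0.42 in log2 CPM (camera adjusted p = 0.0349; adjusted p = 0.494 with an estimated correlation; fry adjusted p = 0.0288) and a lower list score in LYVE-1+ cells of 6 of 6 mice. Without the LYVE-1- library of mouse 2 the median was -0.25 and the list was not called (adjusted p = 0.113), nor was it called when genes that stand in several lists were left out (adjusted p = 0.160). Areg, an epidermal growth factor receptor ligand, fell by 3.33, the protease gene Mmp14 by 1.87, the matrix gene Ecm1 by 1.93 and Tgfb1 by 0.20 on the log2 scale. Vegfa fell by 0.51 on the log2 scale, from 21.2 ± 2.87 to 14.9 ± 3.17 CPM, and Vegfb rose by 0.31, from 11.4 ± 1.30 to 14.1 ± 1.12 CPM (SD, n = 6). Both were chosen after their values were seen. Receptors of VEGF and angiopoietin went both ways, with 3 of 14 members higher and 4 lower over all genes, and 4 and 4 adjusted over the list alone (camera adjusted p = 0.80). Flt4 rose, and so did Tie1 (1.60, chosen after its value was seen), whereas Nrp1 (-2.22) and Notch1 (-0.50) fell. The median of that list was below 0 and its mean above 0. Of 10 angiostatic genes 2 were lower by both adjustments (camera adjusted p = 0.431), Ifng (-2.45) and Sparc (-1.73), and Sparc lost its call without the LYVE-1- library of mouse 2, 3 or 4 or the LYVE-1+ library of mouse 4 or 5, with adjusted p from 0.0531 to 0.0730, and without a filter (0.0724) or without mouse 2 (0.0575). In the hyaluronan list 4 of 13 members were higher, among them Lyve1 and Hmmr (1.65), and 1 lower, by both adjustments (camera adjusted p = 0.696), with a median below 0 (above 0 at equal totals) and a mean above 0. Hmmr is also a member of the cell cycle list. The fibroblast, T cell and NK cell genes above fell in the same libraries, and Mmp14, Ecm1 and Areg are also expressed by such cells. The CD45 and B220 gates should remove fibroblasts, and the source of these transcripts was not tested.

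Trafficking genes were more often lower. Of 31 measured members 16 were lower and 3 higher, by both adjustments (median difference -0.32, camera adjusted p = 0.00515; adjusted p = 0.349 with an estimated correlation), and the list was not called when genes that stand in several lists were left out (adjusted p = 0.0967). The gut-homing genes Itgb7 (-0.50) and Ccr9 (-2.82) fell, and Ccr9 is also a marker of plasmacytoid dendritic cells, whose other transcripts fell in the same libraries. Of 23 cytokine genes 10 were lower and 2 higher, by both adjustments (median difference -0.30, camera adjusted p = 0.0196; adjusted p = 0.222 with an estimated correlation), and the call was lost without the LYVE-1+ library of mouse 5 (adjusted p = 0.0611) and with the share of reads in no annotated gene as a covariate (0.0868). Il22, a product of innate lymphoid and T cells, fell by 3.34 and Bmp7 by 2.54 on the log2 scale. The NF-kB and inflammatory list had 9 of 26 members lower and 1 higher over all genes, and 11 and 2 adjusted over the list alone (median difference -0.19, camera adjusted p = 0.0154; adjusted p = 0.222 with an estimated correlation), with Ccl5 and Ccl4 (-1.02) lower. The mean difference of that list was -0.44, and Ccl5 (-5.87) fell alongside the T and NK cell genes above. In the interferon list 8 of 28 were lower and 0 higher over all genes, and 7 lower adjusted over the list alone (median difference -0.28, camera adjusted p = 0.0112; adjusted p = 0.494 with an estimated correlation), with Bst2 (-0.75), also a marker of plasmacytoid dendritic cells, and Oas1a (-0.51). In the list of immediate-early genes, which tissue dissociation can induce, 8 of 28 were lower and 0 higher over all genes, and 7 lower adjusted over the list alone (median difference -0.36, camera adjusted p = 0.0034; adjusted p = 0.494 with an estimated correlation), with Btg2 (-0.43) and Ier2 (-0.46). With mouse as a block 24 of these 28 were lower and 2 higher. The block also gave 15 lower and 3 higher in the NF-kB and inflammatory list and 13 lower and 0 higher in the interferon list. MHC class II genes had 6 of 16 members lower and 1, Cd80 (0.68), higher over all genes, and 7 and 1 adjusted over the list alone (median difference -0.18, camera adjusted p = 0.0337; adjusted p = 0.616 with an estimated correlation), with Ciita at -0.25. With mouse as a block 11 were lower and 2 higher. That list call was lost without the LYVE-1- library of mouse 1 or 6 or the LYVE-1+ library of mouse 3, 4, 5 or 6, with adjusted p from 0.0614 to 0.0792. MHC class I genes had 8 of 15 lower, among them H2-Q7 (-0.52) and H2-K1 (-0.35), and 1 higher over all genes, and 9 and 1 adjusted over the list alone. The list missed the threshold (camera adjusted p = 0.081) and passed it without the LYVE-1+ library of mouse 1 (adjusted p = 0.0298). The class I genes H2-Q7, H2-K1 and their relatives share sequence, so their values are uncertain.

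Of 31 nuclear genes of oxidative phosphorylation 19 were higher and 0 lower over all genes, and 20 higher adjusted over the list alone (median difference 0.23, camera adjusted p = 1.9e-06; adjusted p = 0.494 with an estimated correlation), with Sdhb at 0.39 and Atp5b at 0.28. With the share of reads in no annotated gene as a covariate, chosen after seeing the data, the median was 0.049 and the call was lost (adjusted p = 0.525). Of 18 glycolytic genes 9 were higher and 1 lower over all genes, and 10 and 1 adjusted over the list alone (median difference 0.18, camera adjusted p = 0.0261; adjusted p = 0.494 with an estimated correlation), with Pkm at 0.38 and Tpi1 at 0.78. The list was not called when genes that stand in several lists were left out (adjusted p = 0.0967), nor with that covariate (median 0.062, adjusted p = 0.448). Of 8 mitochondrially encoded genes 0 were called in edgeR, 0 had an unadjusted p under 0.05 and 0 were called in DESeq2 (camera adjusted p = 0.690), and their share of counts was 0.420% ± 0.06 in LYVE-1+ and 0.408% ± 0.07 in LYVE-1- libraries (SD, n = 6; exact permutation p = 0.71, adjusted p = 0.71). Of 37 ribosomal protein genes 0 were called in edgeR and 0 in DESeq2 without mouse as a block, where 3 had an unadjusted p under 0.05 in edgeR, and with the block 13 were called higher and 2 lower in edgeR. The list was not called without the block (camera adjusted p = 0.236) and was called with it at the preset correlation (adjusted p = 0.0172) but not with an estimated correlation (0.757). It was also called without the LYVE-1- library of mouse 1 (adjusted p = 0.00874). The hypoxia list (3 of 22 higher and 4 lower by both adjustments, camera adjusted p = 0.568) held a rise of Ldha (0.43) and a fall of P4ha2 (-2.96). The unfolded protein response list (4 of 24 higher and 1 lower by both adjustments, camera adjusted p = 0.657) held a rise of Asns (1.29) and a fall of Ern1 (-0.70). The B cell receptor signalling list (2 of 22 higher and 5 lower over all genes, 3 and 5 adjusted over the list alone, camera adjusted p = 0.609) held falls of Malt1 (-0.38) and Cd72 (-0.25). Of 6 measured enterocyte genes Ada rose and Cdh1 (-5.28), which intraepithelial lymphoid cells can also express, fell (camera adjusted p = 0.609; 1 higher and 2 lower adjusted over the list alone). Of 5 secretory epithelial genes Trpm5 rose and Pigr (-0.53) fell over all genes (camera adjusted p = 0.695; 1 higher and 2 lower adjusted over the list alone), with a median below and a mean above 0, and Pigr lost its call with limma-voom, without a filter, and without any 1 of 10 libraries, with adjusted p from 0.0533 to 0.144. The call held without the LYVE-1- library of mouse 2 or the LYVE-1+ library of mouse 6. The list of the 5 sort markers had 1 member higher, Lyve1, and was not called (camera adjusted p = 0.859), with a median below and a mean above 0. Too few members were measured to test the granulocyte and mast cell list, in which Kit fell and 2 of 19 genes were measured, and the enteric neuron and glia list, in which 4 of 13 genes were measured and Tubb3 rose by 1.13. Tubb3 lost its call without the LYVE-1- library of mouse 1 or 4 or the LYVE-1+ library of mouse 2, with adjusted p from 0.0502 to 0.0588, and with limma-voom (0.0794) or without mouse 2 (0.0503). Across the 41 lists tested, camera called 22 at the preset correlation, 0 with an estimated correlation, where 9 had an unadjusted p under 0.05, and fry called 25, of which 20 were shared. The lists that fry called beyond these 20 were the pan-B cell, marginal zone and B1, regulatory B cell, conventional dendritic cell and MHC class I lists, and those it did not call were the extracellular matrix (adjusted p = 0.0658) and MHC class II lists (adjusted p = 0.0533).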

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

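No test in this part was chosen after the result was seen, although Vegfb, Thy1 and Mki67 were named after their values were seen. In 296 groups of 6 libraries, the highest or lowest library stood apart from its neighbours by more than Dixon's 95% limit for 6 values in 19, where chance gives about 14.8. No explanation was weighed for these values.

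Among shares, the LYVE-1+ library of mouse 2 had a mitochondrial share of 0.307%, the LYVE-1- library of mouse 2 an IgD share of 23.6% and an effective number of heavy-chain variable segments of 54.3, and the LYVE-1+ library of mouse 1 a ribosomal protein share of 1.31%. The mitochondrial share was also low in the LYVE-1- library of mouse 2 (0.297%), which was not flagged. Among genes in LYVE-1+ libraries, log2 CPM lay apart from the other 5 libraries for Ptprc (10.53), Lat (1.35) and Ciita (9.07) in mouse 1, for Il4ra (8.95), Vegfb (3.57) and Mki67 (7.08) in mouse 2, for P4ha2 (-3.12) in mouse 4, for Klra7 (-2.45) in mouse 5 and for Nkg7 (-3.18) in mouse 6. Klra7 rested on 3 counts there, and P4ha2 and Nkg7 on 1 count each. In LYVE-1- libraries, log2 CPM lay apart for Derl3 (4.05) and Thy1 (0.97) in mouse 2, for Pecam1 (8.02) and Mcm3 (7.12) in mouse 4, for Oas1a (2.60) in mouse 5 and for H2-Q7 (8.87) in mouse 6.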

How the results depend on the processing

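Alternatives with a correction for GC content and length, without mouse 6 or with the share of reads in no annotated gene as a covariate were chosen after seeing the data. Counts of changed genes stayed within 1.5 times of 4734 except with limma-voom and mouse as a block (7230), against a fold of 1.5 (713) and with the covariate (348). Higher genes numbered 427 against a fold of 1.5, 4021 with the replicate block and the GC content and length correction, and 247 with the covariate. Lower genes numbered 3616 with limma-voom and the block, 286 against a fold of 1.5 and 101 with the covariate. A fold threshold asks for larger changes by construction, and the covariate is correlated with the group (r = -0.840); the cause was not tested for the others. With an estimated correlation camera called 0 of the 41 lists tested, although 9 of the 41 had an unadjusted p under 0.05, and fry called 25. The replicate block called 6399 genes, of which 4689 were shared, and 23 lists at the preset correlation but 0 with an estimated correlation (lowest adjusted p = 0.282). It made Ptprc and the ribosomal protein list called, turned the sign of Adgre1 (-0.13) and the direction of the macrophage list (median -0.056), and at that preset correlation changed no other call among the genes and lists named. Counts of called members rose with the block in many lists, by the most in the immediate-early list, where 24 of 28 were lower and 2 higher against 8 and 0 without it. Lower members rose from 9 to 15 in the NF-kB and inflammatory list, from 8 to 13 in the interferon list, from 6 to 11 in the MHC class II list and from 4 to 9 in the hypoxia list. Higher members rose from 19 to 25 for oxidative phosphorylation, and the unfolded protein response went from 4 higher and 1 lower to 7 and 6. Without mouse 6, 4149 of the calls were shared, and without mouse 2, 4201. Without any 1 library 3788 to 4483 of the calls were shared, and 120 of 128 called genes followed through the alternatives, Lyve1 included, kept their call.

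With the covariate 4 lists lost their call at the preset correlation: oxidative phosphorylation (median 0.049, adjusted p = 0.525), glycolysis (0.062, adjusted p = 0.448), cytokines (-0.25, adjusted p = 0.0868) and extracellular matrix (-0.56, adjusted p = 0.316). MHC class I genes were then called (-0.17, adjusted p = 0.0103). Without mouse 6 the call of MHC class II genes was lost (adjusted p = 0.137) and conventional dendritic cell genes were called (adjusted p = 0.0180). The cause was not tested.

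Reversals were found in results that had not been called, and the cause was not tested. Adgre1 stood at -0.63 with limma-voom, -0.12 with the replicate block and GC content and length correction, and -0.25 with the covariate. With the covariate Ptprc stood at 0.045, and the direction turned for the lists of memory B cells (median -0.13), macrophages (-0.12), VEGF receptors (-0.029), B cell receptor signalling (-0.0015), the unfolded protein response (-0.071) and ribosomal proteins (-0.11). Without genes that stand in several lists it turned for blood endothelium (-0.29), macrophages (0.034) and hyaluronan (-0.18), without mouse 2 for secretory epithelium (0.14) and VEGF receptors (-0.13), and without mouse 6 for blood endothelium (-0.22) and secretory epithelium (-0.47). A list's direction is that of camera, which can differ in sign from its median.

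Leaving out 1 library at a time gave -0.25 to 0.15 for Itgam and -0.42 to 0.32 for Adgre1. List medians ranged from -0.23 to 0.070 for sort markers, -0.34 to -0.047 for blood endothelium, -0.36 to 0.12 for macrophages, -0.42 to 0.41 for secretory epithelium, -0.38 to -0.047 for VEGF receptors and -0.019 to 0.16 for mitochondrially encoded genes. The difference in mitochondrial share ranged from -0.00972 percentage points, without the LYVE-1- library of mouse 2, to 0.0351, without the LYVE-1+ library of mouse 2. With at least 21772937 counts per library, depth limits mainly genes with few counts in a group, such as Klra7 with 3 counts over the LYVE-1+ libraries.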

Other observations

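The test of the lymphatic list without Lyve1 was chosen after the result was seen, and so were the fits with the GC content and length correction and with the share of reads in no annotated gene. Heavy-chain variable segments were used less evenly in LYVE-1+ libraries: their effective number, after thinning to 17052 counts, was 54.6 ± 3.48 against 59.3 ± 2.54 in LYVE-1- libraries (SD, n = 6; exact permutation p = 0.0325, adjusted p = 0.0472), and it was lower in 6 of 6 mice. Reads of similar segments are shared, so single segments were not named. The share of reads aligned to several places was higher, at 25.0% ± 1.18 against 22.7% ± 1.07 (SD, n = 6; exact permutation p = 0.013, adjusted p = 0.0231). Tested by mouse pairs, this share and the effective number of variable segments each stood at the smallest possible p (exact sign-flip p = 0.03125, unadjusted). The ribosomal protein share, 1.06% against 0.987% (exact permutation p = 0.416, adjusted p = 0.475), and the share of the 20 highest genes, 9.70% against 10.4% (exact permutation p = 0.0758, adjusted p = 0.101), did not pass the threshold.

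Single members went against the direction of their lists. The costimulatory ligand gene Tnfsf9 rose by 0.98 in the cytokine list, where 10 of 23 genes were lower and 2 higher. Chosen after their values were seen, the immunoproteasome gene Psmb8 rose by 0.22 while H2-K1 fell by 0.35 on the log2 scale, and the glucose transporter gene Slc2a3 fell by 0.25 on the log2 scale while Pkm rose. Ccl22, also chosen after its value was seen, rose by 0.85 among inflammatory genes. Its call was lost without the LYVE-1+ library of mouse 1 or 3 or the LYVE-1- library of mouse 2, 3 or 4 (adjusted p from 0.0573 to 0.0867) and without a filter (0.0798).

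Lymphatic endothelial genes rose with Lyve1, and depth does not account for this, since the fitted median of the list was 1.60 at equal totals with 9 genes still called higher. B cells that transcribe Lyve1 and no other lymphatic gene are argued against as the only source of this rise, because the 12 members without Lyve1 had a fitted median of 1.55. That median lay above all 10000 random lists matched on expression (the middle 95% of which ended at 0.198). The rise of the list was known when this comparison was chosen, so the comparison adds no support of its own. Whether such B cells were present beside lymphatic endothelial RNA from other cells was not tested. A hypothesis that stays open is that lymphatic endothelial cells, their fragments or their RNA may have entered the LYVE-1+ gate, although the CD45 and B220 gates should remove them. Across the 6 LYVE-1+ libraries Lyve1 varied with the mean of 7 other members called higher (Prox1 was left out because its values had been seen), with r = 0.975 (exact permutation p = 0.00556 over 720 pairings, adjusted p = 0.00556 over 2 relations), rho = 0.886 (exact permutation p = 0.0333, adjusted p = 0.0333) and r = 0.979 without the 2 libraries farthest from the median. Not all of these 7 followed Lyve1 singly. The r was 0.971 for Mmrn1, 0.951 for Ccl21a, 0.919 for Cldn5 and 0.7996 for Flt4. It was 0.221 for Ackr2, 0.206 for Reln and -0.32 for Ackr4. The fitted median of 1.55 lay between Reln (1.53) and Ackr2 (1.57), so it does not show that the list moved with Lyve1 across libraries. Mmrn1 at 30.9 CPM was the most abundant of the members named here, other lists hold 6 of the 13 measured members, and B cells that switch on a wider lymphatic programme were not tested.

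T and NK cell genes fell, and neither scaling nor depth accounts for it, since under 4 scalings and at equal totals the fitted median stayed at -3.21 or lower over all 19 T cell genes, against -3.23 in the fit used here, and at -3.47 or lower over all 12 NK cell genes, against -3.51. Over the 28 genes called lower it stayed at -3.56 or lower, against -3.60. A hypothesis that stays open is that other B220+ cells or their RNA may have been in the LYVE-1- gate, which held no T cell marker in the labels. Across the 6 LYVE-1- libraries these 28 genes varied together, with a median pairwise r of 0.782 where the middle 95% of random lists ended at 0.0954. The LYVE-1- library of mouse 2, made from less RNA, had the highest mean log2 CPM of the T cell (4.81) and NK cell lists (3.91). It was also highest for the plasmacytoid dendritic cell (5.47) and fibroblast lists (4.85). The relation was not tested without that library. Levels were low, with Cd7 at 56.0 CPM, Gzmb at 27.3 CPM and Cd8a at 22.2 CPM in LYVE-1- libraries. No further biological explanation was tested.

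Germinal centre and cell cycle genes rose, and GC content and transcript length do not account for it, since with the replicate block and that correction the fitted median of the 47 genes called higher was 1.52, against 1.45 in the fit used here, and 47 of 47 stayed called. The block entered together with the correction, so the correction was not isolated. With the block alone 35 cell cycle and 13 germinal centre genes were called higher, as many as in the fit used here. RNA quality was not measured directly, and the share of reads in no annotated gene, taken in its place, cannot be told apart from the group. With that share as a covariate the median of these 47 was 1.18 and 17 of the 47 stayed called. The median standard error rose from 0.19 to 0.34, because share and group were correlated (r = -0.840). A candidate explanation is a larger share of germinal centre B cells among LYVE-1+ cells, for which the differences in 14 germinal centre genes and in cell cycle genes went together over the 6 mice (r = 0.973, exact permutation p = 0.00139, adjusted p = 0.00278; rho = 1, exact permutation p = 0.00278, adjusted p = 0.00556; r = 0.995 without the 2 mice farthest from the median). Dividing B cells in general would give such a relation too.

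Of 100 of the 462 splits of the 12 libraries only 1, the real one, called as many genes, with 4734 against 1 in the highest other split. Of the 32 splits that part each mouse's pair, the highest other gave 0, and 1 with the replicate block against 6399. In the other splits the difference between the fractions adds to the spread within groups, which by itself lowers their gene counts. For the lists, 1 of 100 splits, the real one, gave 22 calls with the preset correlation, but the highest other split gave 20 and the median other split 10. Other splits can keep part of the difference between the fractions, so these counts are not a rate of false calls. With an estimated correlation 0 lists were called in the real split, so that a list call at the preset correlation says little by itself.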
